A study of Picea abies with 4 samples.

How the data were processed

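Total RNA from bud, needle and stem of 1 Norway spruce tree and from a pool of tissues was made into PARE libraries and sequenced on an Illumina instrument, per the labels' protocols. The deposited values are counts: each file lists distinct tag sequences with the number of reads of each, not normalised, as the values themselves show. Trimming, length filters and any matching to a genome are not given in the sources used here. Tags were 18 to 46 bases long, and nearly all had 19 to 21 bases. The labels describe the material as small RNA, while the protocol and the series title name PARE. Groups were taken from the tissue label, with 1 library in each of the 4 groups.

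The design, the lists and the alternatives were fixed before the data were examined. The sequences of 30 plant small RNA families and 10 animal miRNAs, used as controls, were written down from general knowledge of conserved families, not from a spruce catalogue. They were divided into transcription factors (15 families), RNA silencing (5), F-box (2), nutrient and copper (6), disease resistance (2) and animal controls (10). No reference transcripts were used here, so the planned placement of tags on transcripts was not run, and tags are reported by sequence and count without gene names.

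For each family and library, reads of tags whose bases 1 to 9 are the complement of miRNA positions 10 to 2 were counted, with position 1 left free. The background was the same 9 bases at offsets 1 to 11 of the tags, each as a rate per 1000000 reads of tags long enough to hold it, and 1000 dinucleotide-shuffled copies of each miRNA. Between tissues, a family was counted as differing when the highest and lowest of the 3 tissues were at least 2-fold apart, their 95% exact Poisson intervals did not overlap and the highest had at least 50 reads. Ratio intervals are exact conditional binomial intervals at 95%, and intervals of shares are Wilson intervals at 95%. A library with 0 reads was set to a floor of 3 reads, which is 0.0575 RPM in bud, 0.076 RPM in needle, 0.051 RPM in stem and 0.0658 RPM in the pool.

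For reconstruction, ends (tags sharing their first 18 bases) with at least 5 reads over the 4 libraries and a penalty of at most 1 over the first 9 bases (1 mismatch or up to 2 G:U pairs, not doubled here) were extended upstream by up to 13 bases. Each step took the base with the most reads among tags overlapping by at least 16 bases, with tags shortened to 20 bases. A site was kept when its penalty against the whole miRNA was 4 or less, where a mismatch counts 1 and a G:U pair 0.5, doubled at positions 2 to 13. The same was done for 20 shuffled copies of each miRNA. The window around a site covered the 11 bases upstream and, for shares of window reads, 2 bases downstream. In the pool, the 9-base value was compared with the range of the tissues widened by the Poisson intervals.

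The families named are the called families, up to 15 by fold over the other offsets and up to 10 by ratio between tissues, which came to 7. Also named are the leading end of each, the leading end of families with reconstructed sites and the 3 most abundant tags of each library. Sharp ends, the miR858 sites and sites other than the leading one of a family were chosen after their values were seen. Comparing tissues at reconstructed sites, and setting ends beside all ends of like abundance (0.5 to 2 times the reads), was also added then. A sharp end, defined after the data were seen, meets the penalty limit of reconstruction over its first 9 bases, and so need not hold the exact complement. It has at least 100 reads, and at least 10 times as many as any other end found within 11 bases upstream and 2 downstream. Positions whose bases were not reconstructed counted as holding no other end, so for many sharp ends the upstream window was only partly checked.

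Shared tags and complexity were measured after random thinning of each library to the total of needle. Probes (14) for nuclear rRNA, organelle or bacterial rRNA, plastid mRNA and adapters counted tags holding 16 or more consecutive probe bases. Alternatives changed the match, the low counts, the counting unit, the tag length, the leading end, the denominator, the size rule, the controls and the settings of reconstruction. The needle library left out, copies at 1 base left out and tags joined by 18 bases were added after the data were seen. A copy at 1 base differs by 1 base from another end of its family with at least 50 times the reads.

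The steps were tested on simulated data with 3000 transcripts. For calls of families, the 12 planted families were called in 48 of 48 library and family pairs, and the others in 0 of 112. All 6 families planted with a 4-fold difference between tissues were found, with a median ratio of 4.10, and 0 of 6 planted without a difference. The pool lay within the tissues for 12 of 12 planted families. In the simulation the background was alike in all tissues apart from counting noise, and the pool was planted as the mean of the tissues. These 2 results therefore do not measure the rate of false differences in the real libraries, where shuffled miRNAs met the rule in 28.5% of cases. All 24 planted sites were reconstructed, together with 4 sites that were not planted. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pyarrow 21.0.0, statsmodels 0.14.6 and matplotlib 3.10.9 were used.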

Results

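PARE, the parallel analysis of RNA ends, sequences the 5′ ends of uncapped, polyadenylated RNA fragments. An Argonaute protein loaded with a miRNA cuts its target opposite miRNA positions 10 and 11, so a tag from a cut target starts opposite position 10. The series asked which transcripts of Norway spruce (Picea abies), a conifer, are cut in this way. It holds 4 libraries from 1-year-old branches of 1 tree, made from bud, needle, stem and a pool of tissues, with 1 library in each group. The bud library held 52218907 reads in 16729993 distinct tags, and the needle library held 39450316 reads in 10625730 distinct tags. For stem the totals were 58826650 reads and 19203494 tags, and for the pool 45623870 reads and 16366431 tags. There were no replicates, so differences between libraries have no replicate check and no test was made between tissues. The values compare these libraries, not the tissues in general. Levels are in reads per 1000000 reads of a library (RPM) with 95% exact Poisson intervals, which cover counting error only, since reads without molecular identifiers are not independent molecules.

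In bud, stem and the pool the strongest signature by fold over the other offsets belonged to miR166, which in land plants targets HD-ZIP III transcription factors. Tags starting with the complement of miR166 positions 10 to 2 reached 71.7 RPM (69.5 to 74.1) in bud, 4.46 RPM (3.83 to 5.17) in needle, 122 RPM (119.0 to 125) in stem and 51.4 RPM (49.4 to 53.5) in the pool. These levels were 156, 6.77, 199 and 90.2 times the median of the same 9 bases at offsets 1 to 11 inside the tags. With the exact 10-base match, which includes position 1, the folds fell to 1.5 in bud, 4 in needle, 3.63 in stem and below that of bud in the pool, and miR166 lost its call in every library. For miR160, which in land plants targets auxin response factor (ARF) transcripts, the fold over the other offsets was 13.3 in bud, 13.8 in needle, 13.3 in stem and 21.3 in the pool, so that miR160, like miR167 at 12.3, stood above miR166 in needle. The matching ends of miR319, a family that targets TCP transcription factors, stood 3.05-fold above the other offsets in bud, 2.89-fold in stem and 4.13-fold in the pool.

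A family was called in a library when offset 0 exceeded every other offset, was at least 2-fold above their median and reached the 99th percentile of 1000 shuffled miRNAs. Of 30 plant families, 6 were called in bud, 3 in needle, 5 in stem and 5 in the pool, where shuffled sequences gave 0.256, 0.252, 0.271 and 0.238 expected calls. In the list of transcription factor families, 5 of 15 were called in at least 1 library, namely miR156, miR160, miR166, miR167 and miR319. In the RNA silencing list the 2 of 5 called families were miR390 and tasiR-ARF, the small RNA against ARF transcripts that miR390 helps to produce. None of the 2 F-box families, the 6 nutrient and copper families, the 2 disease resistance families or the 10 animal miRNAs, which plants lack, was called in any library. The 3 families miR160, miR166 and miR167 were called in all 4 libraries. tasiR-ARF was called in bud at 19.3 RPM (18.1 to 20.5) and in stem at 15.6 RPM (14.6 to 16.6). It was not called in needle at 16.2 RPM (14.99 to 17.5, 2.52-fold) or in the pool at 16.5 RPM (15.3 to 17.7, 2.62-fold), levels no lower than in stem. miR390 was called only in bud, at 21.4 RPM (20.2 to 22.7), and miR156, which targets SPL transcription factors, only in the pool, at 15.3 RPM (14.2 to 16.5). Of 8 alternatives, 4 lost the miR390 call and 3 the miR156 call, while 2 calls of miR390 were gained elsewhere.

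A single 5′ end carried much of several signatures, where an end is the set of tags sharing their first 18 bases. For miR166 the end CCTGGTCCGGATGCTATT held 9810 reads, 73.0% of the family's matches (72.3% to 73.8%, Wilson interval), and for miR160 the end GAGCCAGGCATGATCGCA held 3526 reads, 80.9% (79.7% to 82.1%). The miR167 matches rested on GGCAGCTTCCTCGACGAC, with 7533 reads or 94.4% (93.8% to 94.8%), and the bases reconstructed upstream of it did not pair with miR167 (penalty 11.5, against a limit of 4 for a site). Without the most abundant end of each family, miR167 fell to 0.40-fold in bud and 0.99-fold in needle. The calls of miR160 in needle (1.52-fold), miR156 in the pool (2.59-fold, its only call) and tasiR-ARF in bud (2.49-fold) and stem (1.83-fold) were lost as well, while tasiR-ARF gained one in needle (3.52-fold). The leading ends of the others were TCTTCTGTCATTTCAATC for miR156 (332 reads), TTCAGTCCAGTTCAAGTC for miR319 (539 reads), TCCTGAGCTTCTCTGTCC for miR390 (619 reads) and AGGTCAAGAAATGTCACC for tasiR-ARF (1098 reads). The calls depended on weighting by reads: with each distinct tag counted once, 1 family was called in bud, 0 in needle, 1 in stem and 1 in the pool. With up to 1 mismatch allowed they numbered 2, 1, 3 and 2.

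**Figure D1:**
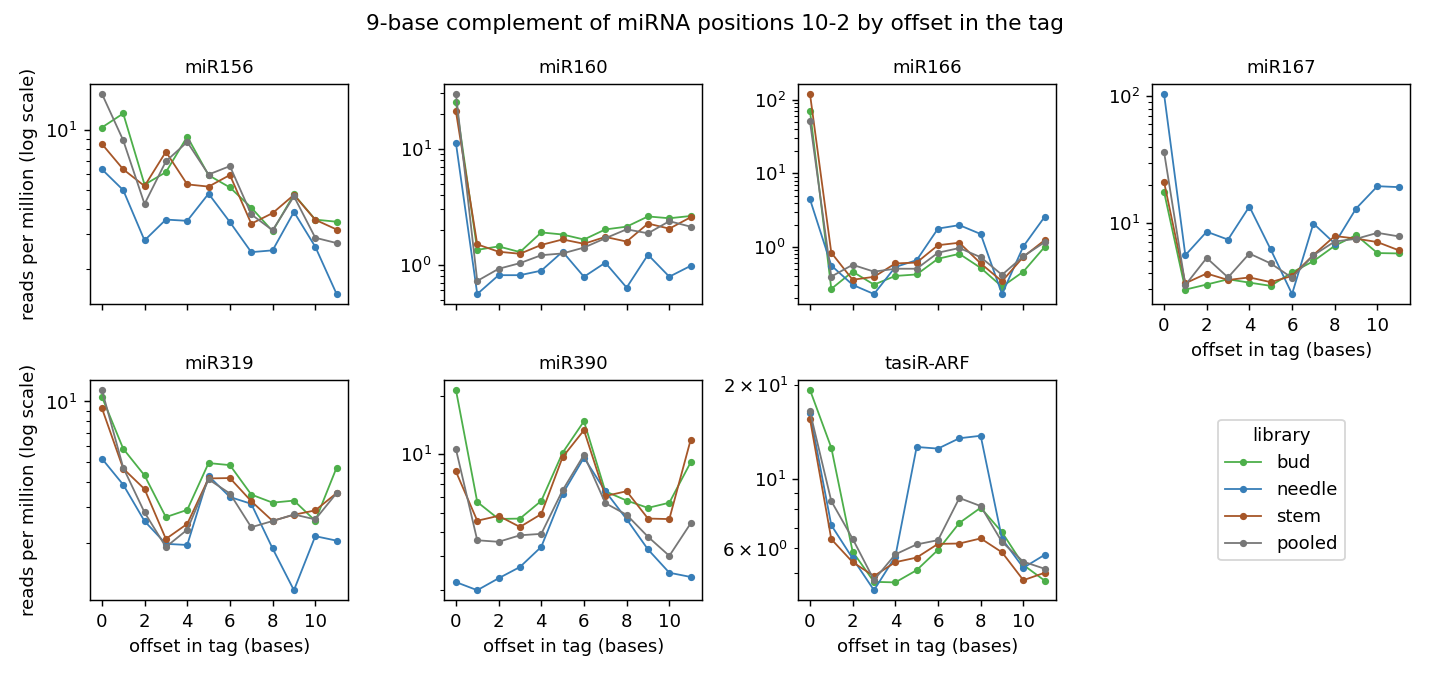
RPM (log axis) of tags that hold the 9-base complement of miRNA positions 10 to 2 at each offset from 0 to 11 in the tag (horizontal axis, bases), 1 panel per called family and 1 line per library. For miR166 the value at offset 0 was 122 RPM in stem and 4.46 RPM in needle, and for miR167 it was highest in needle at 105 RPM.

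Whole target sites were recovered for families that the 9-base match alone did not call. Overlapping tags extended each end upstream, and the joined sequence was paired with the full miRNA. The end TCAGGATTCTCACCCCAA lay in a miR172 site, a family that targets AP2-like transcription factors, with 7617 reads over the 4 libraries and a penalty of 1.5, and held 98.8% (98.5% to 98.98%, Wilson) of the reads within the window around it. For miR169, which targets NF-YA transcription factors, TTCTTGGCTGTTTGTGTA had 6356 reads (penalty 4, 85.4% of its window), and for miR396, which targets growth-regulating factors, AGCTGTGGGAAAACATGG had 3817 reads (penalty 3, 95.5%). A miR393 site, of a family that targets auxin receptor F-box transcripts, paired with a penalty of 1 at TCCCTTTGGATGTCATCC and had 763 reads, 97.6% of its window. Both miR166 sites read CTGGGATGAAGCCTGGTCCGG, and the 4 miR390 sites had 1644 reads together.

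In total 47 sites were recovered for the plant families. Shuffled copies of the same miRNAs gave a mean of 4.4 sites (1 to 9 over 20 sets), so the real count was 10.7 times that mean, and the animal miRNAs gave 1 site. The site end exceeded every end in the 11 bases upstream for 25 plant sites, 53.2%, against 15.9% for shuffled sites. More sites than in any of the 20 shuffles were found for 8 families: miR156, miR166, miR169, miR171, miR396 and miR529 among transcription factor families, miR390 in the RNA silencing list and miR393 in the F-box list. All 4 miR529 sites lie on the sequences of miR156 sites, with their ends 4 bases upstream of those of miR156. None of the nutrient and copper or disease resistance families passed that mark. The 2 sites of miR172 and the 3 of tasiR-ARF were equalled in number by 1 of 20 shuffles, and in reads by 0. These counts hold ends that differ by 1 base from another site with at least 50 times the reads, 3 of the 5 miR169 sites, 1 of the 2 miR172 sites and 1 of the 7 miR396 sites. Without them miR169 (2) and miR396 (6) stayed above the most in any shuffle, 0 and 3. Ends that share their first bases can also be given the same upstream bases, so the sites are not all separate sequences. Within each of miR166, miR171, miR529 and tasiR-ARF all sites read the same, as do most miR156 sites. Counted by distinct sequence, miR156, miR166, miR171 and miR529 would not exceed the most sites of any shuffle (2, 1, 1 and 2), which were counted by end. A penalty limit of 3 left 23 sites and a limit of 5 gave 73.

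**Figure D2:**
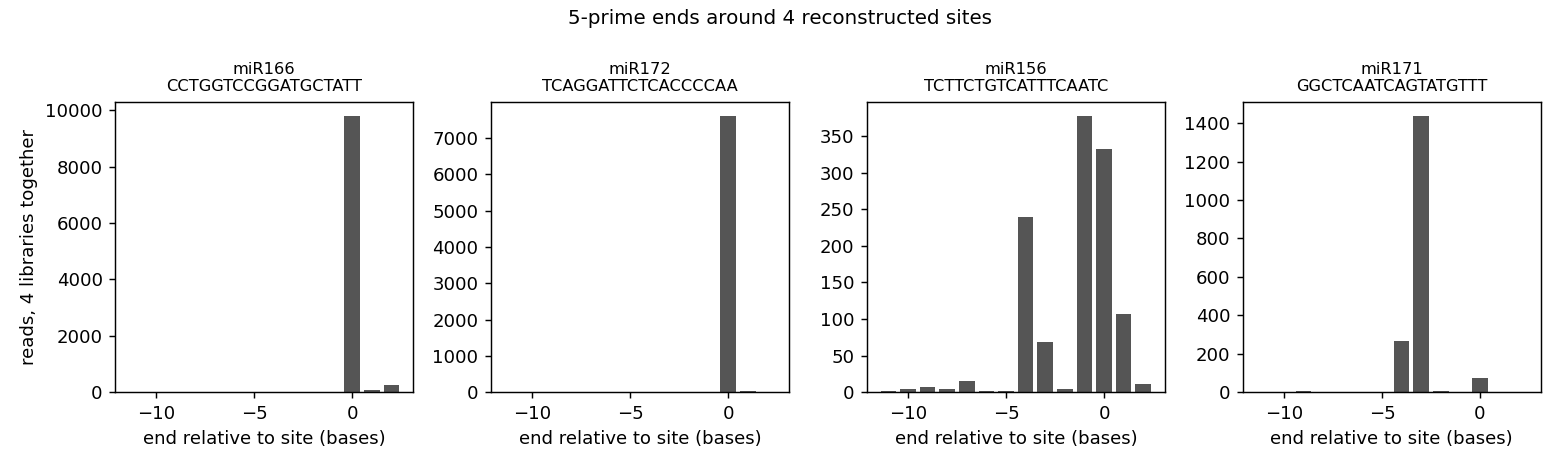
Reads over the 4 libraries (vertical axis) of 5′ ends from 11 bases upstream to 2 bases downstream of the site end (horizontal axis, bases), for the most read reconstructed site of miR166, miR172, miR156 and miR171. The end at 0 holds 96.6% of window reads for miR166 and 98.8% for miR172, while for miR171 the end 3 bases upstream holds 79.9%.

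The needle library was lowest for most families with reconstructed sites. Of the 12 families with at least 50 reads at their sites, 10 were lowest in needle and 11 were 2-fold or more apart between the highest and lowest tissue with a ratio interval above 1, a comparison added after the data were seen. The miR166 sites had 100.2 RPM in stem, 55.9 in bud and 3.37 in needle, a stem-to-needle ratio of 29.7 (25.0 to 35.6). At the miR169 sites the levels were 69.2 RPM in bud, 25.0 in stem and 1.19 in needle, a bud-to-needle ratio of 58.1 (43.6 to 79.2). miR390 sites had 1148 reads in bud, 135 in stem and 3 in needle, and the bud-to-needle ratio was 289 (98.7 to 1404). The miR393 site had 355 reads in bud and 2 in needle, a ratio of 134 (36.9 to 1112).

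Sites of miR396 ran the other way, with bud lowest. They reached 50.1 RPM in stem, 8.47 in needle and 0.574 in bud, a stem-to-bud ratio of 87.2 (61.0 to 130). The miR172 sites were less uneven, at 54.4 RPM in stem, 45.5 in bud and 8.01 in needle. At the tasiR-ARF sites bud had 10.99 RPM and needle 4.08 RPM, a ratio of 2.69 (2.26 to 3.23). Within the miR390 family, TCTTGAGCTTATATTACA had 520 reads in bud and 0 in both needle and stem, so that it was at least 131-fold higher in bud than in needle, counting 0 as 3 reads. Between bud and stem alone, without the needle library, 6 of the 12 families were 2-fold or more apart, among them miR390 at 9.58 (8.01 to 11.5) and miR529, on miR156 sequences, at 5.60 (3.92 to 8.21), both higher in bud.

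**Figure D3:**
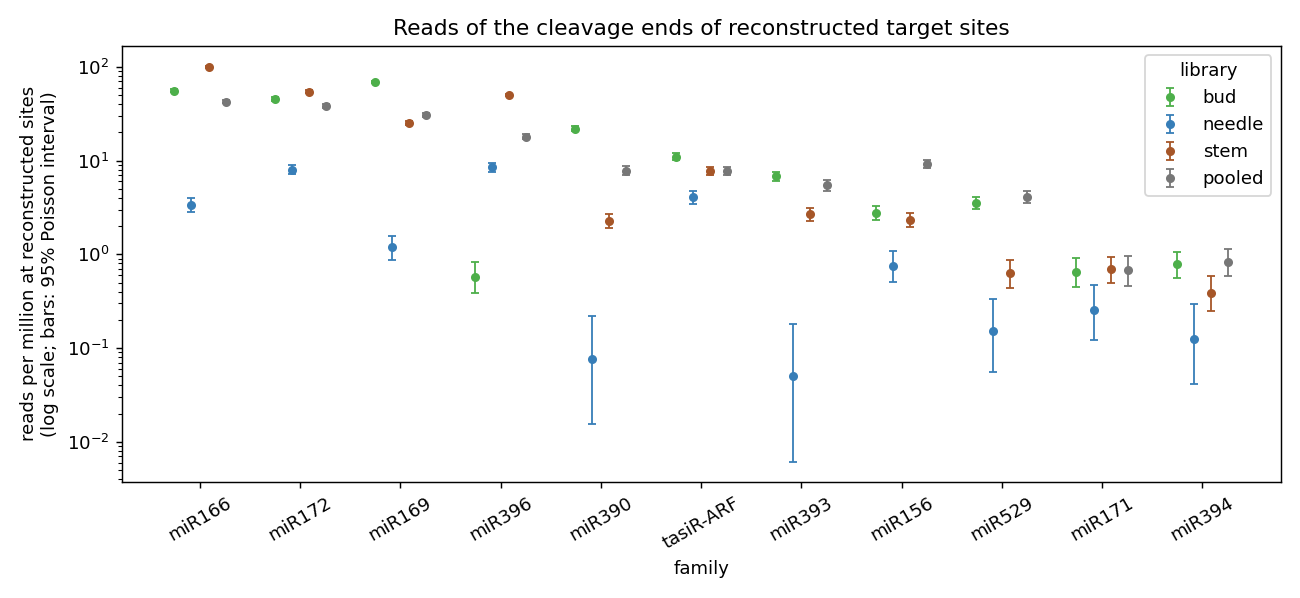
RPM (log axis) of the cleavage ends at reconstructed sites, for each family with at least 100 reads at its sites (horizontal axis), with 1 point per library and bars for the 95% Poisson interval. Needle is lowest for miR166 at 3.37 RPM and for miR169 at 1.19 RPM, while bud is lowest for miR396 at 0.574 RPM.

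By the 9-base match, miR166, miR390, miR319 and, except in 3 alternatives, miR160 were also lowest in needle, and miR167 was highest there. The ratios were 27.3 (23.5 to 31.9) for miR166 between stem and needle, 9.72 (7.81 to 12.2) for miR390 between bud and needle, and 5.95 (5.54 to 6.40) for miR167 between needle and bud. miR160 had a bud-to-needle ratio of 2.25 (2.02 to 2.51) and miR319 one of 2.02 (1.72 to 2.39), although its leading end was lowest in bud, at 1.13 RPM against 1.80 in needle and 3.08 in stem. miR156 at 1.62 and tasiR-ARF at 1.24 stayed below 2-fold. For miR396 the match differed from the sites: it was highest in bud, with a ratio of 1.17 to needle. Of 30 families, 13 were at least 2-fold apart with intervals that did not overlap, 12 of them lowest in needle, 10 highest in bud, 2 in stem and 1 in needle. Shuffled miRNAs met the same rule in 28.5% of cases, equal to 8.56 of 30 families, and 60.4% of these were lowest in needle. Over 9 alternatives the rule was no longer met in 1 for miR166, 2 for miR390, 1 for miR167, 5 for miR319 and 2 for miR160, whose ratio fell below 1 in 3 more, to 0.83 with tags of 20 bases alone. Without the needle library 4 families differed, of which miR390 (2.63 between bud and stem) was called.

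Differences of 2-fold or more were common among 5′ ends of all kinds. Of 207190 ends with at least 100 reads, 75.8% were 2-fold or more apart between tissues, with a median ratio of 3.75. Among 64 ends with at least 100 reads at reconstructed sites or matched and sharp, a comparison added after the data were seen, 4 exceeded the 95th percentile of ends of like abundance, including the miR166 end CCTGGTCCGGATTCTATA at 96.2. Of the 64 entries, 57 were 2-fold or more apart with intervals that did not overlap. The 75.8% for all ends was counted without a rule on intervals. The miR166 end with the most reads stood at the 77.2 percentile, the leading miR169 end at 81.6 and the leading miR396 end at 91.4. The leading miR390 end stood at 89.9 and the miR393 end at 94.1.

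The labels do not say which tissues, in what amounts, make up the pool, so the other libraries are not known to be its parts. Its 9-base value fell within the range of bud, needle and stem for 5 of the 7 called families, among them miR166 at 51.4 RPM and miR167 at 36.6 RPM. miR156 at 15.3 RPM and miR160 at 29.8 RPM (28.3 to 31.5) were above every tissue. The share among shuffled miRNAs was 97.8%. At reconstructed sites the pool lay between the tissues for 9 of the 12 families with at least 50 reads and above every tissue for 3. Among the latter, miR156 had 9.14 RPM (8.28 to 10.1) in the pool against 2.76 in bud, 2.33 in stem and 0.76 in needle. A non-negative least squares fit of the pool on the tissues over 2374720 shared ends gave weights of 0.113 for bud, 0.384 for needle and 0.451 for stem (R squared 0.927), which describe the fit and not a known mixture. Leaving out the 100 most abundant ends moved them to 0.194, 0.251 and 0.459 (R squared 0.67).

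The most read end of the needle library, carried by GAATAGCTATAGAACGATGAC, GAATAGCTATAGAACGATGA and GAATAGCTATAGAACGATG, the 3 most read tags there, held 990729 reads, 2.51% of needle (2.51% to 2.52%, Wilson), against 0.254% in bud, 0.323% in stem and 1.20% in the pool. In bud the most read tags were ATTCGTGCGAAAGGTGGTGC (66009 reads) and ATGGCAGGGCGGAGGCCTACC (62773 reads), followed by GAATAGCTATAGAACGATGAC (60598 reads). Stem was led by GAATGCATCGGATGGATGCCC (113956 reads) before GAATAGCTATAGAACGATGAC (94605 reads) and TGCGACCCCAGCTCAGGCGA (84588 reads). The last was among the 3 most read in the pool as well, with 93025 reads, after GAATAGCTATAGAACGATGAC (246291 reads) and GAATAGCTATAGAACGATGA (226522 reads). The 100 most abundant tags took 2.49% of reads in bud, 8.17% in needle, 2.89% in stem and 4.59% in the pool. Needle also had more short tags, with 21.95% of reads at 19 bases against 7.996% in bud, 6.34% in stem and 9.06% in the pool. Counting bounds of these shares of libraries lay within 0.0129 percentage points.

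Thinned to the depth of needle, bud held 13937447 distinct tags, stem 14558701 and the pool 14774639, against 10625730 in needle. Pairs of libraries shared a median of 31.8% of distinct tags (29.0% to 35.3% over 6 pairs) and 67.3% of reads (62.5% to 69.4%). The Spearman correlation across tags with at least 10 reads in either library, which are not independent replicates, was highest between bud and stem at 0.264 and lowest between bud and needle at -0.266. Leaving out tags low in both libraries lowers this correlation, so a value below 0 does not show opposite profiles. Probes for nuclear rRNA matched 2268 RPM in bud, 2280 in needle, 1501 in stem and 1827 in the pool, nearly all from the start of the 18S rRNA. Adapter probes matched 821 RPM in bud, 221 in needle, 187 in stem and 102 in the pool. The 2 organelle or bacterial rRNA probes gave 5.59, 13.1, 11.97 and 16.9 RPM. The 2 plastid mRNA probes matched 1 read in needle and 0 in the others. In bud the upper bound of the interval for 0 reads was 0.0706 RPM.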

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

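The alternatives without the needle library, without copies at 1 base and with tags joined by 18 bases were chosen only after the data were seen. No paired analysis was possible because each group has 1 library and the labels give no replicate numbers. Counts of called families changed most with the counting unit. With each distinct tag counted once, 1, 0, 1 and 1 families were called in bud, needle, stem and the pool. Allowing 1 mismatch gave 2, 1, 3 and 2, and the offsets alone as control gave 11 in bud and 6 in needle. In stem, 2 were called with the exact 10-base match, and without the leading end 3 were called in stem and 3 in the pool. Other alternatives stayed within 1.5-fold of the reported counts.

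Families that differed between tissues numbered 4 with 1 mismatch, 2 with distinct tags, 8 when divided by the other offsets, 7 under a 3-fold rule and 4 without the needle library. At reconstructed sites 6 families differed without the needle library, against 11 with it. The pool lay within the tissues for a number of called families within 1.5-fold of that reported in all alternatives. Reconstructed sites numbered 28 with 18 bases of overlap, 23 with a penalty of 3 and 73 with a penalty of 5, and 42 without copies at 1 base. With tags read once left out, the libraries held 4708914 (bud), 3600815 (needle), 4299807 (stem) and 4316516 (pool) distinct tags, and pairs shared 42.4% of distinct tags and 73.1% of reads. With tags joined by 18 bases the shares were 37.5% and 75.2%.

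Among the named families, 162 of 224 alternative folds kept their call or its absence, 37 lost the call and 8 gained it. The other 17 fell below 1, 13 for miR167 and 4 for miR160. Of 63 ratios between tissues, 48 kept their side of the rule, 11 no longer met it, 1 newly met it and 3 fell below 1. For miR167 the 10-base match gave 0.432 in bud, 0.75 in needle, 0.227 in stem and 0.754 in the pool. Without its leading end the folds were 0.402, 0.993, 0.557 and 0.73. Distinct tags gave 0.547 in bud, 0.579 in stem and 0.769 in the pool, and 1 mismatch gave 0.901 in bud and 0.835 in stem. miR160 fell to 0.961 in bud and 0.951 in stem with distinct tags, and to 0.708 in needle and 0.982 in stem with 1 mismatch. Its bud-to-needle ratio was 0.967 with distinct tags, 0.827 with tags of 20 bases alone and 0.962 when divided by the other offsets. The cause was not tested, except that a leading end holds 94.4% of miR167 matches. For miR166, the 10-base match gave 1.5 in bud, 4 in needle, 3.63 in stem and less than in bud in the pool, so the call was lost in every library. Both reconstructed miR166 sites have G where the complement of position 1 is A, so that match leaves their ends out. In needle it was also lost with 1 mismatch and distinct tags (2.1). Without its leading end, miR160 in needle fell to 1.52 and miR156 in the pool to 2.59, and both lost the call. Depth limits low values in needle, where the miR390 sites rest on 3 reads.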

Other observations

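The sharp ends, the positions around sites, and the tests of denominators, of random sets of ends, of groups of related ends, of miR167, of related miR482 ends and of reading errors were chosen only after their results were seen. Sharp ends, much stronger than the other ends found on the bases reconstructed around them, allowed up to 1 mismatch or 2 G:U pairs in their first 9 bases. There were 56 for plant families, against a mean of 14.4 for shuffled miRNAs (6 to 29) and 0 for the animal miRNAs. Many had few or no upstream bases reconstructed, so their surroundings were not fully checked. The family miR482, which in land plants targets disease resistance transcripts of the NBS-LRR class, had 11 such ends with 17276 reads, more than any of its 20 shuffles, and levels of 111 RPM in bud, 21.8 in needle, 114 in stem and 86.0 in the pool. None of these ends was reconstructed as a site within the penalty limit. Most were not extended over the whole miRNA, however, so their full pairing was not scored. The most read end (4975 reads) had a penalty of 4 over 19 of 22 positions. An end with 108 reads had 5 over 12 positions. The ends with 3618 and 2970 reads were known over all 22 positions, with a penalty of 11. Of the 11, 0 start with the exact 9-base complement, by which miR482 had 2.57 RPM in bud, 2.18 in needle and no call. miR396 also had 11, with 13961 reads and a stem-to-bud ratio of 7.14 (6.71 to 7.61), against 87.2 at its reconstructed sites. The most read of these sharp ends (6713 reads) had a penalty of 6 over all 21 positions, and others reached up to 14. Only those with 3817 and 174 reads were scored over the whole miRNA within the limit of 4. miR319 had 6, led by TTCAGTCCTTACGTACGC, which is outside the exact match, with 1801 reads in bud, 682 in stem and 2 in needle, a bud-to-needle ratio of 680 (188 to 5622).

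Some reconstructed sites had their strongest end beside the position opposite miRNA position 10. Both miR171 sites, of a family that targets GRAS transcription factors, paired with a penalty of 0, but the strongest end lay 3 bases upstream, with 1439 reads or 79.9% of the window at GGCTCAATCAGTATGTTT and 288 reads or 77.8% at GGCTCAATCAGCATCTCT. All 4 miR858 sites, of a family that targets MYB transcription factors, peaked 1 base upstream, with 999, 345, 128 and 43 reads. The miR858 sites did not stand above chance, however, since 1 of 20 shuffles had as many sites. Their 58 reads were equalled by 2 of the shuffles, with up to 202. At the 6 miR156 sites reads were spread over the positions 4 bases upstream (468), 3 upstream (351), 1 upstream (611) and 0 (728), with an end shared by several sites counted once. The upstream pair held 38.2% (34.7% to 41.8%, Wilson) of these reads in bud, 49.1% (44.6% to 53.7%) in stem, 34.5% (31.5% to 37.7%) in the pool and 7.89% (3.67% to 16.2%) of 76 reads in needle. Without the most read site the shares were 40.7%, 62.3%, 40.2% and 9.30%. The 4 miR529 ends, led by TCTCTCTTCTGTCATTTC with 239 reads, all lie 4 bases upstream of miR156 ends and are among the reads counted there, so miR529 is not a separate set of transcripts here.

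The needle library was lowest for 77.8% of 63 miRNA-matched ends, which are not independent, since many lie on related sequences. Joined by sequence they form 40 groups, and the leading ends were lowest in needle for 72.5%, against a median of 52.5% and 95% limits of 37.5% and 67.5% in 10000 random sets of ends of like abundance, and with whole families joined for 88.2% of 17 groups against an upper limit of 76.5%. These shares exceeded those of ends of like abundance in general. The random sets were matched by abundance alone, however, while the matched ends were also chosen as sharp or as reconstructed. The comparison therefore cannot tell a general lack of ends in needle, acting through that choice, from a property of the matched ends. Without the 100 most abundant tags in the denominators the share was still 70% of the 40 groups (upper limit 67.5%), which argues against these tags as the whole cause. On the 26 sequences with 10 or more upstream reads in needle and bud together, ends 6 to 60 bases upstream had a median needle-to-bud ratio of 0.284 (0.147 to 1.05, groups resampled), against 0.179 (0.0993 to 0.388) for the matched ends themselves. Less of these transcripts in needle may therefore account for the low ends, but the interval of the upstream ends reaches 1.05, so such a loss is not shown. A lower rate of cutting, with or without such a loss, cannot be excluded, since the intervals overlap. The 63 matched ends also include sharp ends with penalties up to 14, above the limit of 4 for a site, which may not be cut sites. Both ratios come from the same sequences, and no interval is given for their difference within a sequence.

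For miR167, needle was 5.95-fold above bud, and 1 end with bases upstream that do not pair held most of the reads. Without this end the ratio was 2.92 (2.18 to 3.95, from 150 and 68 reads). Ends that differ from it by 1 base after the first 9 were not removed, and reading errors of this end could be among them. The test therefore cannot tell whether this end alone accounts for the difference. The same 9 bases at the other offsets also had a higher median in needle, 8.52 RPM against 4.06 RPM in bud, and no biological explanation was tested.

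Sharp ends of miR482 were tested against chance matches over 9 bases, with the same mismatches allowed for shuffled sequences. Of 56 upstream bases known, 62.5% could pair with miR482, against a median of 50% for shuffled 3′ parts, and the real value lay above 93.6% of them. These bases are not independent, since ends given the same upstream bases were each counted. The ends with 3618 and 2970 reads, with a penalty of 11, share the same upstream bases. Those with 4975 and 617 reads share others, with a penalty of 4 over 19 of 22 positions. The pooled share therefore cannot decide between chance and pairing. As many as 11 sharp ends were reached by 1 of 200 shuffled sequences (mean 0.545), so separate chance matches would seldom give this number. The ends are related, however, and joined at up to 4 differences in 18 bases they form 2 groups, which 8.5% of the shuffled sequences equalled. Matched ends share much of their first 9 bases, so true targets may be joined by this rule as well. The count of groups therefore cannot tell chance matches to related transcripts from targets, and chance matches may still explain the ends. Reading errors are argued against, since 0 of the 11 ends lie 1 base from any end with 50 times the reads, although 4 have a more read end at 1 base, up to 15.5-fold.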
